A study of Homo sapiens with 18 samples.

How the data were processed

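RNA was taken from core needle biopsies of the right lobe of 6 lean human livers on normothermic machine perfusion, at 0 h (before perfusion), 3 h and 6 h, and kept in a stabilising solution, per the labels' protocols. Libraries were made from poly(A) RNA with a kit that does not mark strand, per the labels' protocols. Viability was set by the submitters, per the labels, from perfusate lactate falling below a set level together with further functional criteria in the first hours. Fatty livers are not analysed here.

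The 18 deposited files hold 1 raw count per gene, made by the authors from sequenced reads, per the submitters' processing notes. Reads were written with bcl2fastq 2.17, trimmed with Trimmomatic 0.36, aligned to hg38 with STAR 2.5.2b and counted per gene with featureCounts of Subread 1.5.2, per the submitters' processing notes. The strand setting, the annotation release and the handling of reads that map to several places are not given in the sources used here. All values were whole numbers of 0 or more in each of the 18 files, as counts of this kind are. Each file lists 57500 gene identifiers, of which 56410 matched a gene symbol in the reference annotation and 488 further ones were named from GENCODE. The 518 genes on chromosome Y and the genes XIST and TSIX were left out of every table. No pair of the 153 pairs of libraries was identical (smallest chi-square per degree of freedom 24.9).

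All further values were computed here. Total counts per library were 23742338 to 33744966, and mitochondrial genes (35 in the annotation) held 5.91% of them on average. Library sizes were scaled by TMM, and CPM values use these scaled sizes. Genes were kept by edgeR's expression filter over the 6 groups (minimum count 10, minimum total count 15, large group size 10, minimum share 70%), which left 17485. Each gene was fitted with edgeR 4.0.16 (R 4.3.3) by a robust quasi-likelihood model with 1 coefficient for each viability and time group, and contrasts were tested by its F test with Benjamini-Hochberg adjustment within each contrast and a threshold of 0.05. The common biological coefficient of variation was 0.389. Log2 CPM values use a prior count of 2, standard errors come from the fitted model, and the principal components use all tested genes. Folds from groups with a count of 0 throughout are given as floors, with 3 counts in place of 0.

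12 contrasts were tested: 3 h against 0 h, 6 h against 0 h and 6 h against 3 h over all livers with both classes weighted alike, 3 h and 6 h against 0 h within each class, the difference of these changes between classes at 3 h and 6 h, and viable against nonviable livers at 0, 3 and 6 h. The 3 h and 6 h contrasts share their 0 h libraries, so no overlap or correlation between them is given. 24 gene lists and 10 marker lists written out from textbook knowledge were tested with camera of limma 3.58.1 (preset correlation between genes 0.01), again with the correlation estimated from the residuals, and with fry, each adjusted over the lists of a contrast. Counts adjusted over the list alone apply the Benjamini-Hochberg adjustment to the members of that list.

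The genes named in the text follow a rule. Among genes past the threshold with a mean log2 CPM of at least 1 and a symbol, and with the same sign in every liver (changes over time) or with classes that do not overlap (viability), the 8 largest increases and 8 largest decreases could be named. From each list that is described, up to 4 measured members with the smallest p could be named, past the threshold or not. Some genes that this rule allowed are not reported here, and counts of named genes include them. Sample groups, contrasts, alternatives, lists and this rule were set before the data were examined, and the lists described for each contrast were picked afterwards.

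Replicate numbers within a class were taken as the same liver at the 3 times. The labels agree in all 18 samples, through a liver code that stands in the field meant for lean or fatty, while that value stands in the field meant for the code. Deviations from the group means correlated within livers, with 18 pairs of libraries at 0.282 to 0.731 (median 0.539), and each of the 18 pairs correlated best with its own liver. The numbers therefore pair the samples. The fit without the pairing was set as the first, and the fit with the liver as a replicate block is given where it changes a call or moves a count more than 1.5 times. That paired fit called 1499 genes at 3 h over all livers, against 799 without the block. Between classes no block can be fitted, and there the repeated samples of a liver count as independent in the shared spread.

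Alternatives were DESeq2 1.42.0, limma-voom with a correlation within livers (0.411), RLE size factors, no expression filter beyond a total count of 1, the replicate block, leaving out each liver in turn, fits to the libraries of 1 class or 1 time alone, and the 2 other list tests. Other size factors moved the median change of all genes by at most 0.0295.

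The gene tests were checked on simulated counts with these groups, each library drawn independently and without an effect of the liver. The rates therefore do not cover the correlation within livers or what leaving out the pairing does. In these counts 100 genes of log2 size 1 and 100 of size 2 were made to change. For the 3 h change over all livers edgeR recovered 46% and 92% of these, for the 3 h change within viable livers 10% and 73%, for the difference of changes 1% and 31%, and for viable against nonviable at 0 h 9% and 80%. Its false calls were 6.12%, 1.19%, 8.57% and 4.3% of all calls, against 24.1%, 15.1%, 18.5% and 18.2% for DESeq2. At 3 against 3 livers the smallest exact p is 0.1, so single values between classes carry no exact test. Because reads shared between near-identical genes cannot be assigned, values of HSPA1A, HSPA6, the metallothioneins and the serum amyloid genes are uncertain, and antisense genes cannot be told from the genes they overlap. Plots were made with matplotlib 3.10.9 in Python 3.11.15.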

Results

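Poly(A) RNA sequencing measured gene expression in needle biopsies of 6 lean human livers that had been declined for transplantation. The livers were kept warm and oxygenated on a machine that perfused them with a red cell solution. Every liver was sampled before perfusion (0 h) and after 3 h and 6 h on the device. 3 livers cleared lactate and met further criteria of bile, flow, pH or glucose handling and were classed as viable. The other 3 did not and were classed as nonviable, giving 18 libraries in 6 groups of 3. The total count per library was 27594844 ± 2584185 (mean ± SD, n = 18). Group means at 0, 3 and 6 h were 25946084, 28863122 and 27449139 in viable livers and 28183760, 26360500 and 28766457 in nonviable livers (n = 3 each). Between 22866 and 27593 genes had a count in each library, and mitochondrial transcripts held 2.88% to 11% of it. In all, 17485 genes were tested. Changes are given as log2 ± SE with adjusted p from edgeR, and levels as CPM, mean ± SD over livers. The first principal component carried 33.6% of the variance and placed the 0 h libraries of all 6 livers at its low end, between -70.65 and -49.82.

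**Figure D1:**
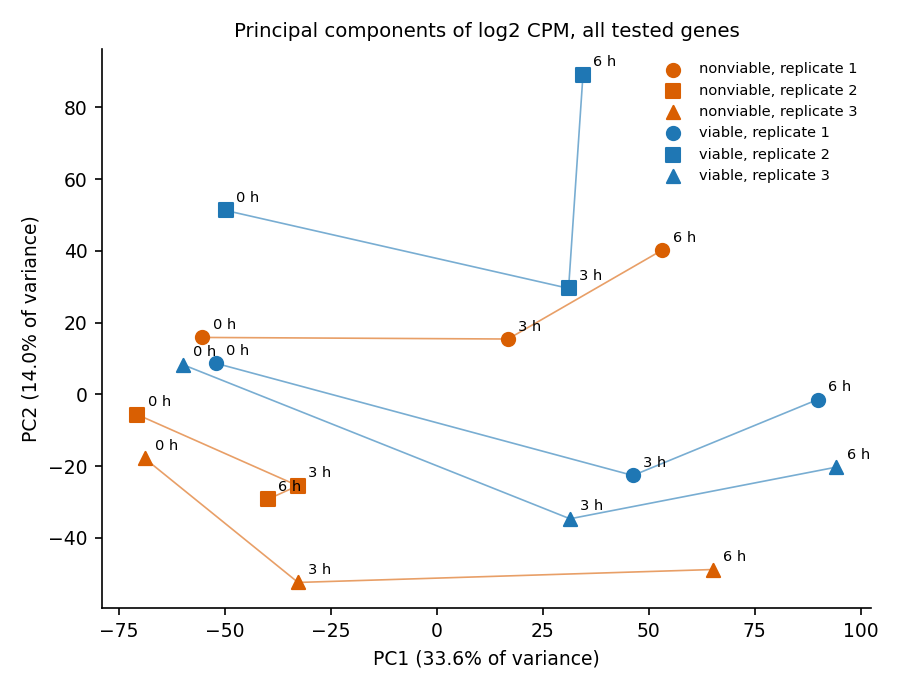
Principal components of log2 CPM in 18 libraries, with the 3 time points of each liver joined. PC1 (33.6%) separated the 0 h libraries from all perfused ones, and nonviable replicate 2 moved least between 0 h and 6 h (-70.65 to -39.93).

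The first 3 h of perfusion were compared with 0 h over all 6 livers to ask what warm perfusion does to liver tissue of either class. Immediate early transcription factors rose in every liver. KLF4 (chromosome 9, minus strand), a Kruppel-like factor, rose from 3.87 ± 0.52 to 44 ± 13.3 CPM (3.46 ± 0.20, adjusted p = 2.08e-07, n = 6). FOSB (chromosome 19, plus strand), an AP-1 subunit, rose from 0.335 ± 0.249 to 101 ± 63.5 CPM (8.25 ± 0.86, adjusted p = 0.000425). Its partner JUND rose by 3.18 ± 0.35, and the stress factor ATF3 from 7.53 ± 1.92 to 489 ± 321 CPM (5.86 ± 0.73). All 26 measured members of the immediate early list rose (26 adjusted over the list alone), with a median of 3.58 (camera adjusted p = 1.5e-70). Of 17 cytosolic chaperones 15 rose (17 adjusted over the list alone), with a median of 2.57 (camera adjusted p = 1.16e-33). HSPB1 (HSP27) went from 109 ± 28.6 to 1170 ± 684 CPM (3.24 ± 0.34), and the exchange factor HSPH1 rose by 4.47 ± 0.68 and the co-chaperone BAG3 by 5.03 ± 0.79. HSP90AA1 rose from 706 to 3760 CPM (2.26 ± 0.37, adjusted p = 0.00326). Over alternatives its adjusted p ran from 4.8e-08 to 0.0522, the highest without viable replicate 3.

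Inflammatory and clotting genes rose with them at 3 h. Of 25 NF-kappaB cytokines, chemokines and adhesion molecules 19 rose (22 adjusted over the list alone), with a median of 4.34 (camera adjusted p = 4.81e-35). The neutrophil chemokine CXCL8 rose from 2.09 ± 1.17 to 324 ± 387 CPM (6.92 ± 1.01, adjusted p = 0.0023). The monocyte chemokine CCL2 rose from 2.12 ± 0.806 to 75.7 ± 59.2 CPM (5.05 ± 0.68), the leukocyte ligand ICAM1 by 3.53 ± 0.52 and the NF-kappaB inhibitor TNFAIP3 by 4.30 ± 0.67. IL6 rose by 6.88 ± 1.38 (adjusted p = 0.00972). That call was lost in 4 of 6 fits without 1 liver, and its adjusted p ran from 1.7e-08 to 0.31 over all alternatives (0.0928 without viable replicate 3). Of 11 genes of clotting and fibrinolysis control 6 rose (8 adjusted over the list alone), with a median of 2.64 (camera adjusted p = 7.92e-13). The urokinase receptor PLAUR rose by 3.74 ± 0.47, THBS1 by 3.08 ± 0.42 and thrombomodulin, THBD, by 2.83 ± 0.44. Of 18 hypoxia and glycolysis genes 5 rose (5 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 6.23e-05). They included the glycolytic regulator PFKFB3 (2.42 ± 0.35) and adrenomedullin, ADM (2.58 ± 0.43). Over this interval the immediate early, chaperone, NF-kappaB, hypoxia and clotting calls held with an estimated correlation (adjusted p = 0.0072, 0.0346, 0.0375, 0.013 and 0.013). With a replicate block as well, chaperones were at adjusted p = 0.0703 and no longer held, while immediate early genes did (0.00382).

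Other stress and repair lists moved in part at 3 h. Of 18 unfolded protein and integrated stress genes 2 rose (4 adjusted over the list alone, 4 with a replicate block; camera adjusted p = 0.000773, adjusted p = 0.407 with an estimated correlation). These were PPP1R15A (GADD34), from 9.3 ± 1.87 to 214 ± 120 CPM, and CHAC1 (3.32 ± 0.85), while ATF4 was at 0.65 ± 0.22 (adjusted p = 0.114, 0.0304 with a replicate block). Of 18 growth factor and liver repair genes 4 rose (5 adjusted over the list alone; camera adjusted p = 0.000555, adjusted p = 0.175 with an estimated correlation). The EGF receptor ligand HBEGF went from 0.853 ± 0.363 to 25.2 ± 16.6 CPM (4.84 ± 0.78), and SOCS3, a brake on cytokine signalling, rose by 3.09 ± 0.56. Of 15 p53 targets and apoptosis genes 6 rose (9 adjusted over the list alone; camera adjusted p = 2.09e-06, adjusted p = 0.267 with an estimated correlation). Among them were MCL1, from 243 ± 26.8 to 1064 ± 617 CPM, and the cell cycle inhibitor CDKN1A (2.85 ± 0.61). KRT19 (2.61 ± 0.52) was among the 2 of 8 cholangiocyte markers that rose (3 adjusted over the list alone, 4 with a replicate block; camera adjusted p = 0.00892, adjusted p = 0.564 with an estimated correlation). Calls lost without 1 liver had highest adjusted p of 0.222 (CHAC1) and 0.0619 (MCL1) without viable replicate 1, 0.0681 (SOCS3) and 0.115 (CDKN1A) without viable replicate 3, and 0.104 (KRT19) without nonviable replicate 1. The lowest over alternatives were 0.000189, 3.3e-06, 1.3e-07, 1.7e-05 and 1.2e-05.

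Fewer genes fell than rose at 3 h. The purinergic receptor P2RY13 fell from 8.19 ± 3.25 to 2.02 ± 0.775 CPM (-2.02 ± 0.39), and the glycosyltransferase GCNT1 from 4.51 ± 1.29 to 1.48 ± 0.59 CPM (-1.63 ± 0.26). The myeloid nuclear antigen MNDA (-1.78 ± 0.33), the chemokine receptor CXCR2 (-1.70 ± 0.43) and the potassium channel KCNJ10 (-1.68 ± 0.33) fell too. Without 1 liver the adjusted p rose to 0.0686 (P2RY13) and 0.0737 (KCNJ10, both nonviable replicate 1), 0.0642 (MNDA, viable replicate 1) and 0.176 (CXCR2, viable replicate 3), against lowest values of 7.1e-06, 1.2e-05, 6e-06 and 0.00115. 2 of 10 neutrophil markers fell (3 adjusted over the list alone; median -0.64, camera adjusted p = 0.000148, adjusted p = 0.407 with an estimated correlation). None of 10 macrophage markers passed (median -0.53, camera adjusted p = 0.0515, 0.00499 with a replicate block). With an estimated correlation and no block, this list was not among the 5 that passed at 3 h. None of 16 hepatocyte plasma protein genes passed either (median -0.06; SERPINC1, -0.15, adjusted p = 0.767). In total 731 genes rose and 68 fell at 3 h, 748 of the 799 in the same direction in all 6 livers. Every gene named above as risen or fallen did so too. Of all tested genes 24.9% kept 1 direction in all 6 livers. Counts were 1364 by DESeq2 (797 shared), 1573 by limma-voom (753 shared) and 1499 with a replicate block (783 shared), and 126, 513, 159 and 203 without viable replicates 1, 2 and 3 and nonviable replicate 1. Of 45 named genes past the threshold 20 stayed past it in all 6 fits without 1 liver, among them KLF4, FOSB, JUND, ATF3, CXCL8 and HSPB1.

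After 6 h, compared with 0 h over all 6 livers, the same lists were also higher. All 17 chaperones rose (17 adjusted over the list alone; median 3.51, camera adjusted p = 5.41e-14, adjusted p = 0.275 with an estimated correlation). So did 24 of 25 NF-kappaB genes (24 adjusted over the list alone; median 4.90, camera adjusted p = 1.02e-17, adjusted p = 0.273 with an estimated correlation) and 25 of 26 immediate early genes (26 adjusted over the list alone; median 2.93, camera adjusted p = 9.1e-19, adjusted p = 0.259 with an estimated correlation). IL6 reached 135 ± 148 CPM (9.57 ± 1.48, adjusted p = 0.000567). CXCL8 reached 677 ± 676 CPM (8.28 ± 1.07), the lymphocyte chemokine CCL20 246 ± 224 CPM (8.21 ± 1.14) and CCL2 170 ± 132 CPM (6.32 ± 0.72). The NF-kappaB subunit RELB rose by 2.87 ± 0.35, ICAM1 by 4.13 ± 0.54 and the AP-1 subunit FOSL1 by 7.52 ± 0.86. HSPB1 reached 1248 ± 621 CPM (3.51 ± 0.35, adjusted p = 0.000102). Of 11 clotting genes 10 rose (10 adjusted over the list alone, 1 down with a replicate block; median 2.57, camera adjusted p = 2.01e-08, adjusted p = 0.125 with an estimated correlation). The urokinase gene PLAU rose by 4.80 ± 0.62 and PLAUR by 4.03 ± 0.48. 9 of 18 hypoxia and glycolysis genes rose (9 adjusted over the list alone; median 0.47, camera adjusted p = 0.00556, adjusted p = 0.125 with an estimated correlation), including ALDOA (0.78 ± 0.14) and hexokinase 2, HK2 (1.86 ± 0.36).

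Oxidant defence and repair genes also rose by 6 h. Of 14 NRF2 antioxidant genes 6 rose (7 adjusted over the list alone, 1 down with a replicate block; camera adjusted p = 0.0171, adjusted p = 0.544 with an estimated correlation). The cystine transporter SLC7A11 went from 0.219 to 9.07 CPM (5.52 ± 0.90) and thioredoxin reductase TXNRD1 from 99.1 ± 50.9 to 568 ± 347 CPM (2.55 ± 0.55). HMOX1 rose by 1.49 ± 0.44 in 5 of 6 livers (adjusted p = 0.0199, range 0.0028 to 0.0932, the highest without viable replicate 3). 2 of 8 metallothioneins rose (3 adjusted over the list alone, 5 with a replicate block; camera adjusted p = 0.109, 0.0174 with a replicate block), a family whose members share reads. MT1A rose by 1.48 ± 0.35 (adjusted p range 0.000353 to 0.0634) and MT2A from 1251 to 3048 CPM (1.28 ± 0.36, range 0.000459 to 0.11), the highest of both without nonviable replicate 1. Of 18 growth and repair genes 10 rose and 1 fell (10 and 2 adjusted over the list alone, 2 down with a replicate block; camera adjusted p = 0.0124, adjusted p = 0.406 with an estimated correlation). HBEGF rose by 5.01 ± 0.78, the EGF receptor ligand AREG by 7.19 ± 1.31 and the oncostatin M receptor OSMR from 30.2 to 70.5 CPM (1.23 ± 0.27). Of 8 cholangiocyte markers 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.109, 0.00362 with a replicate block). KRT19 rose by 3.34 ± 0.53 and KRT7 by 2.66 ± 0.54.

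Few members of the metabolic lists passed at 6 h. PPARA, the receptor that drives fatty acid oxidation, fell from 185 ± 18.6 to 73.3 ± 21.3 CPM (-1.36 ± 0.18, adjusted p = 0.000281). CPT2 (-0.79 ± 0.22) fell with it, at adjusted p up to 0.0779 without viable replicate 3 (lowest 0.00159). Of 15 fatty acid oxidation genes 3 fell and 1 rose (2 up and 4 down adjusted over the list alone, 7 down with a replicate block), and the list median of -0.28 and mean of 0.06 differed in sign (camera adjusted p = 0.258). Of 19 bile acid synthesis and transport genes 3 fell (3 adjusted over the list alone, 11 down and 1 up with a replicate block; median -0.41, camera adjusted p = 0.0124, adjusted p = 0.277 with an estimated correlation). The sterol exporter ABCG8 fell from 97.6 ± 13.3 to 34.1 ± 27.5 CPM (-1.65 ± 0.27) in 6 livers, and its partner ABCG5 (-0.92 ± 0.20) and the bile acid receptor NR1H4 (-1.34 ± 0.26) fell in 5 of 6. Of 13 urea cycle and amino acid genes CPS1 fell, in 5 of 6 livers (-1.06 ± 0.34, adjusted p = 0.032, range 0.000164 to 0.119, the highest without nonviable replicate 3). None of that list passed adjusted over the list alone and 10 fell with a replicate block (median -0.51, camera adjusted p = 0.0171, adjusted p = 0.534 with an estimated correlation). Of 18 drug metabolism genes only the sulfotransferase SULT2A1 fell, in 5 of 6 livers (-0.89 ± 0.28, adjusted p range 0.000594 to 0.129, the highest without viable replicate 3). That list had 0 genes adjusted over the list alone and 13 with a replicate block (camera adjusted p = 0.066, 0.000266 with a replicate block). With an estimated correlation and no block, no list passed at 6 h over all livers. None of 16 plasma protein genes passed (0 adjusted over the list alone; median -0.14, camera adjusted p = 0.112), and 4 fell with a replicate block. Among those 4, F9 was at -0.45 ± 0.17 (adjusted p = 0.0583, 0.00515 with a replicate block).

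Neutrophil, macrophage and platelet genes fell by 6 h. 7 of 10 neutrophil markers fell (7 adjusted over the list alone; median -1.24, camera adjusted p = 4.98e-07, adjusted p = 0.273 with an estimated correlation). The Fc receptor FCGR3B went from 11.1 ± 4.38 to 0.94 ± 1.15 CPM (-3.69 ± 0.48), CXCR2 from 4.14 to 0.373 CPM (-3.58 ± 0.48) and MNDA fell by 2.84 ± 0.35. Of 10 macrophage and Kupffer cell markers 4 fell (7 adjusted over the list alone, 9 with a replicate block; median -1.29, camera adjusted p = 0.000316, adjusted p = 0.485 with an estimated correlation). MS4A7 went from 41 ± 14.2 to 8.32 ± 5.01 CPM (-2.31 ± 0.34), and VSIG4 (-1.45 ± 0.45) and the complement subunit C1QB (-1.33 ± 0.43) fell with adjusted p of 0.105 and 0.117 without viable replicate 1 (lowest 0.000603 and 0.00103). P2RY13 (-3.74 ± 0.43), KCNJ10 (-3.57 ± 0.37), the chemerin receptor CMKLR1 (-3.40 ± 0.41) and GPR34 (-3.11 ± 0.33) fell in all 6 livers. Of 5 platelet markers ITGA2B (-1.69 ± 0.56) and PPBP (-1.68 ± 0.60) fell (3 adjusted over the list alone; camera adjusted p = 0.0341, adjusted p = 0.455 with an estimated correlation). Their highest adjusted p were 0.115 (without nonviable replicate 3) and 0.137 (without viable replicate 3), and their lowest 0.0056 and 0.00688. Of 10 T and NK cell markers 2 rose (2 adjusted over the list alone; median 0.255, camera adjusted p = 0.546). None of 10 endothelial markers passed (1 fell with a replicate block; median -0.15; CDH5, 0.26, adjusted p = 0.418). In total 3259 genes rose and 1565 fell at 6 h, 2900 of the 4824 in the same direction in all 6 livers. Of all tested genes 24.5% kept 1 direction in all 6. limma-voom called 7582 (4703 shared) and the fit with a replicate block 7856 (4794 shared), and 2704, 2513 and 2710 passed without viable replicates 1 and 3 and nonviable replicate 3. Of 65 named genes past the threshold 49 stayed past it in all 6 fits without 1 liver.

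**Figure D2:**
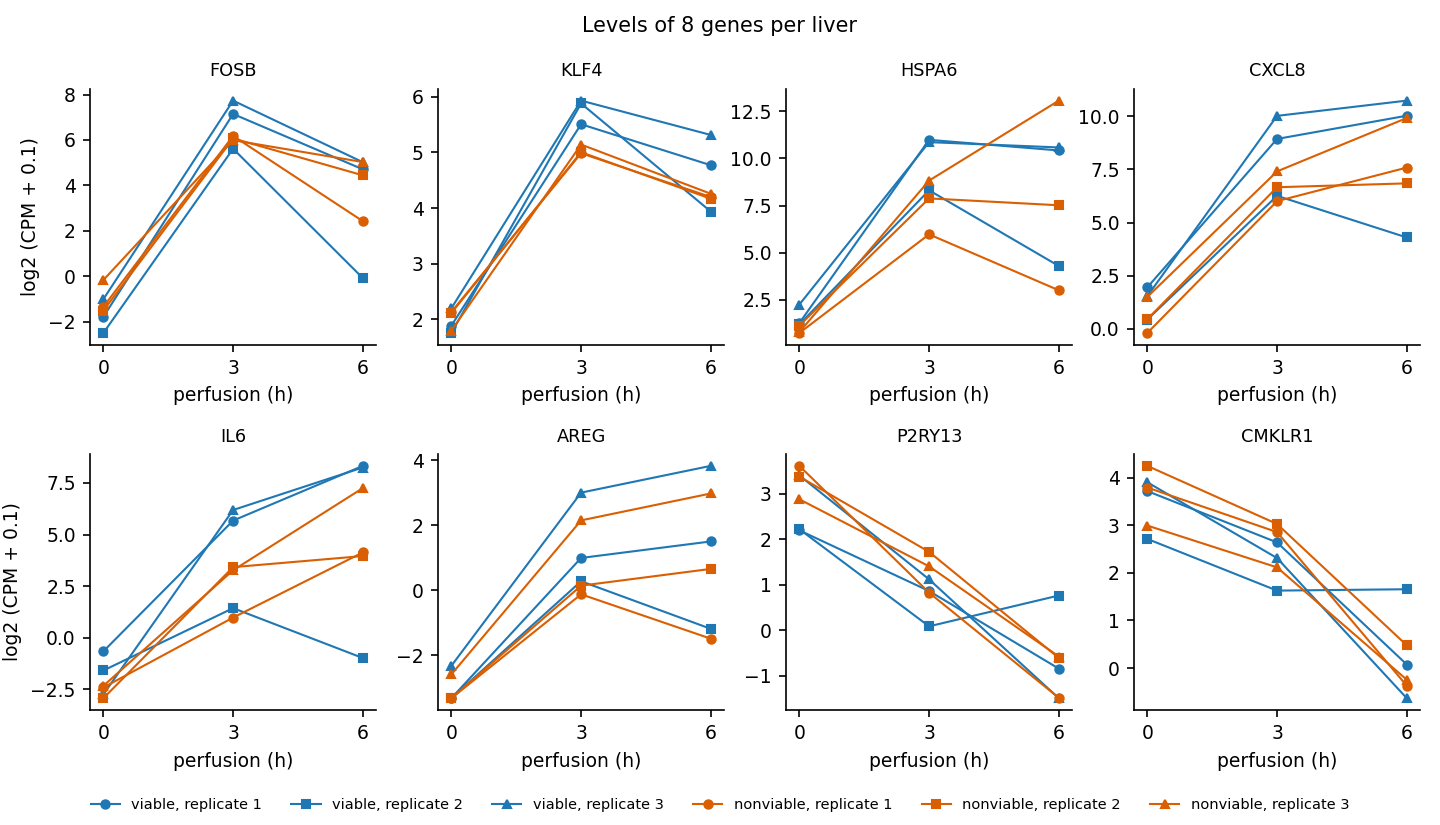
Levels of 8 genes in each liver at 0, 3 and 6 h, log2 of CPM + 0.1. FOSB peaked at 3 h (101 ± 63.5 CPM, n = 6) and IL6 averaged 135 ± 148 CPM at 6 h, with viable replicate 2 below the other livers at 6 h for both.

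The step from 3 h to 6 h was tested over all 6 livers to ask which changes were still under way. The chemokine CXCL11 rose from 0.834 ± 0.468 to 31.2 ± 31.2 CPM (5.22 ± 0.87, adjusted p = 0.0281, n = 6) and CXCL10 from 5.84 to 127 CPM (4.44 ± 0.90). The monocyte chemokine CCL8 (3.31 ± 0.76), the integrin ITGB3 (2.30 ± 0.41) and the transcription factor GLIS3, from 6.23 to 24.2 CPM (1.87 ± 0.20), rose too. KLF4 fell again from 44 to 22.9 CPM (-0.93 ± 0.18, adjusted p = 0.0299). It was the 1 of 26 immediate early genes that passed (2 adjusted over the list alone, 6 with a replicate block; median -0.76, camera adjusted p = 1.94e-05, adjusted p = 0.832 with an estimated correlation). PPARGC1A, a coactivator of gluconeogenesis, fell from 68.7 to 21.4 CPM (-1.57 ± 0.34), the 1 of 13 gluconeogenesis genes to pass (3 adjusted over the list alone, 5 with a replicate block; camera adjusted p = 3.71e-05, adjusted p = 0.553 with an estimated correlation). PCK1, which encodes a key enzyme of that path, went from 2184 to 632 CPM (-1.61 ± 0.43, adjusted p = 0.0689, 0.0294 with a replicate block). MS4A7 fell further (-1.78 ± 0.33), the 1 of 10 macrophage markers to pass (1 adjusted over the list alone, 6 with a replicate block; camera adjusted p = 0.000364, adjusted p = 0.832 with an estimated correlation). FCGR3B (-2.50 ± 0.47), the formyl peptide receptor FPR3 (-1.48 ± 0.20) and FGD2 (-1.48 ± 0.22) fell beside it. 156 genes rose and 64 fell, against 1262 by DESeq2 (217 shared), 2009 by limma-voom (215 shared) and 2398 with a replicate block (219 shared). Without viable replicates 1, 2 and 3 the count was 0, 8 and 1, and without nonviable replicates 1, 2 and 3 it was 1, 872 and 0. None of 17 named genes stayed past the threshold in all 6 such fits, with highest adjusted p from 0.109 (GLIS3) to 0.257 (CCL8), both without nonviable replicate 3, and lowest values of 8.9e-15 and 0.000234.

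Viable livers alone were asked how the 3 that met the criteria changed. At 3 h KLF4 rose from 3.79 ± 0.63 to 55 ± 8.44 CPM (3.86 ± 0.29, adjusted p = 9.1e-06, n = 3), and FOSB to 134 ± 82.1 CPM (9.27 ± 1.28). ATF3 reached 720 ± 304 CPM (6.85 ± 1.08), CXCL8 537 ± 485 CPM (7.69 ± 1.48) and the cytokine IL1B 122 CPM from 0.875 (7.11 ± 1.59), each rising in 3 of 3 livers. 21 of 26 immediate early genes rose (26 adjusted over the list alone; median 4.27, camera adjusted p = 9e-51, adjusted p = 0.0184 with an estimated correlation). 16 of 25 NF-kappaB genes rose (22 adjusted over the list alone; median 5.37, camera adjusted p = 2.2e-27, adjusted p = 0.0828 with an estimated correlation). MNDA (-1.97 ± 0.48), KCNE3 (-2.05 ± 0.46) and GCNT1 (-1.80 ± 0.38) fell. In total 376 genes rose and 23 fell, and DESeq2, limma-voom and the replicate block gave 973, 887 and 969. Without viable replicates 1, 2 and 3 the count was 1, 149 and 1, and of 23 named genes KLF4 alone stayed past the threshold in all 6 fits without 1 liver. The others reached 0.191 (FOSB, without viable replicate 1; lowest 1.8e-19) to 0.404 (GIMAP1, without viable replicate 3; lowest 0.00157).

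At 6 h in viable livers 18 of 26 immediate early genes rose (24 adjusted over the list alone; camera adjusted p = 1.08e-12, adjusted p = 0.386 with an estimated correlation). 21 of 25 NF-kappaB genes rose (24 adjusted over the list alone; camera adjusted p = 1.08e-12, adjusted p = 0.407 with an estimated correlation). The score of that list rose by 1.481 in viable replicate 2, against 5.527 and 5.874 in the other 2. IL6 reached 209 ± 181 CPM (9.49 ± 2.02), the itaconate enzyme ACOD1 42.8 CPM (9.49 ± 2.37), and CCL20 rose by 8.76 ± 1.65. The venular chemokine receptor ACKR1 rose from a count of 0 at 0 h by at least 281-fold, to 951 counts. CPS1, the first urea cycle enzyme, fell from 2319 ± 1133 to 676 ± 272 CPM (-1.78 ± 0.50, adjusted p = 0.0209). It was 1 of 13 in its list (1 adjusted over the list alone, 11 with a replicate block; camera adjusted p = 0.00246, adjusted p = 0.462 with an estimated correlation). The adrenergic receptor ADRA2B (-4.55 ± 0.93) and FCGR3B (-4.14 ± 0.71) fell too. Of 10 macrophage markers MS4A7 fell (1 adjusted over the list alone; -1.63 ± 0.47), with C1QB at -0.47 (adjusted p = 0.593; list median -0.27, camera adjusted p = 0.34). In total 2417 genes rose and 1283 fell, 3636 of 3700 in 3 of 3 livers. Of all tested genes 61.6% kept 1 direction in these livers. limma-voom and the replicate block gave 6384 and 6941, and without viable replicates 1 and 3 the count was 205 and 1. KLF4 alone of 25 named genes stayed past the threshold in all 6 fits without 1 liver. The others reached 0.0667 (KCNJ10, without viable replicate 3; lowest 2e-09) to 0.182, and CPS1 0.138 without viable replicate 1 (lowest 0.000289).

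Nonviable livers alone had a single gene past the threshold at 3 h, KLF4, from 3.96 ± 0.51 to 32.9 ± 1.98 CPM (3.05 ± 0.28, adjusted p = 0.000152, n = 3). Its adjusted p ran from 9.3e-21 to 0.0947, the highest without nonviable replicate 3. FOSB was at 7.24 ± 1.14 in 3 of 3 livers (adjusted p = 0.1, 0.0107 with a replicate block) and JUND at 2.76 ± 0.48 (adjusted p = 0.165, 0.0408 with a replicate block). 25 of the 26 immediate early genes passed adjusted over the list alone and 11 with a replicate block, and the list rose (median 2.95, camera adjusted p = 5.2e-82, adjusted p = 0.0032 with an estimated correlation). DESeq2, limma-voom and the replicate block gave 142, 17 and 39 genes, and 807 were at unadjusted p < 0.05. 29 passed without viable replicate 2 and 0 without nonviable replicate 3.

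At 6 h in nonviable livers 11 of 25 NF-kappaB genes rose (21 adjusted over the list alone, 17 with a replicate block; camera adjusted p = 4.54e-20, adjusted p = 0.117 with an estimated correlation). CXCL8 went from 1.58 to 427 CPM (8.08 ± 1.5), CCL2 from 1.51 to 121 CPM (6.32 ± 1.02), and ICAM1 rose by 4.02 ± 0.76. 12 of 17 chaperones rose (17 adjusted over the list alone, 7 with a replicate block; camera adjusted p = 1.78e-17, adjusted p = 0.123 with an estimated correlation). HSPB1 went from 111 to 1057 CPM (3.25 ± 0.49) and HSPH1 rose by 5.29 ± 1.00, with HSPA6 at 10.70 ± 2.29 (adjusted p = 0.0273, 0.0524 with a replicate block). The matrix protease MMP10 rose from a count of 0 at 0 h by at least 394-fold, to 1069 counts. Such floors, like intervals, cover counting error only. MPEG1 (perforin-2) went from 48.7 ± 16.5 to 4.96 ± 3.79 CPM (-3.29 ± 0.51, adjusted p = 0.00545) and MS4A7 from 50 ± 13.3 to 6.3 ± 2.33 CPM (-2.98 ± 0.49). P2RY13 (-4.42 ± 0.63), CXCR2 (-4.33 ± 0.71) and CMKLR1 (-3.89 ± 0.59) fell as well. 1 of 10 macrophage markers fell (9 adjusted over the list alone, 9 with a replicate block; median -2.22, camera adjusted p = 1.25e-12, adjusted p = 0.117 with an estimated correlation). Its member C1QA was at -2.01 ± 0.55 (adjusted p = 0.0638, 0.00425 with a replicate block). 4 of 10 neutrophil markers fell (9 adjusted over the list alone, 7 with a replicate block; median -1.95, camera adjusted p = 1.74e-14, adjusted p = 0.0876 with an estimated correlation). In total 270 genes rose and 159 fell, 422 of 429 in 3 of 3 livers. Of all tested genes 39.5% kept 1 direction in these livers. Nonviable livers fitted alone gave 124 genes, 59 up and 65 down. With all livers fitted, DESeq2, limma-voom and the replicate block gave 1325, 924 and 1148. Without viable replicates 1 and 3 the count was 76 and 170, and without nonviable replicates 1, 2 and 3 it was 23, 959 and 0. None of 25 named genes stayed past the threshold in all 6 such fits, with highest adjusted p from 0.0699 (MPEG1; lowest 5e-09) to 0.644 (MMP10; lowest 1.2e-06), both without nonviable replicate 3.

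**Figure D3:**
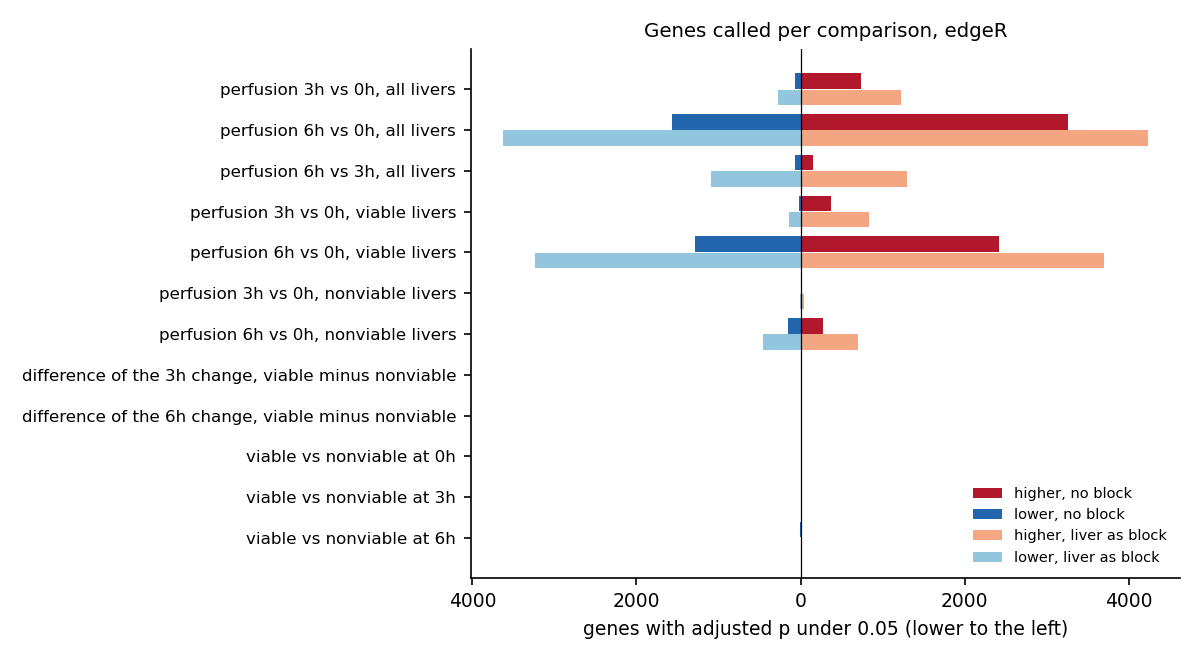
Genes with adjusted p under 0.05 in each comparison by edgeR, without and with a replicate block. The 6 h change over all livers gave 4824 and 7856 genes, and no difference of the changes between classes gave any.

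Whether the 2 classes changed differently was tested as the difference of their changes, viable minus nonviable, n = 3 each. No gene passed at 3 h by edgeR (180 at unadjusted p < 0.05), by DESeq2, by limma-voom or with a replicate block. MYC changed by 4.76 ± 1.19 in viable and 2.10 ± 0.85 in nonviable livers (mean ± SD; difference 2.53 ± 1.05). KLF4 changed by 3.84 ± 0.27 and 3.04 ± 0.27 (difference 0.81 ± 0.37) and ATF3 by 6.77 ± 0.55 and 4.83 ± 0.38 (difference 1.99 ± 1.20), each at adjusted p = 1 for the difference. All 26 members of the immediate early list had a positive difference and 0 passed (0 adjusted over the list alone; median 1.03, camera adjusted p = 1.9e-10, adjusted p = 0.376 with an estimated correlation). At 6 h no gene passed by edgeR either (1057 at unadjusted p < 0.05), with 17 by DESeq2, 0 by limma-voom, 0 with a replicate block and 1 without nonviable replicate 2. Macrophage markers differed as a list, 10 of 10 positive and 0 past the threshold (0 adjusted over the list alone; median 1.83, camera adjusted p = 1.6e-08, adjusted p = 0.368 with an estimated correlation). C1QA was at -0.17 ± 0.58 in viable and -2.10 ± 0.86 in nonviable livers, and MS4A7 at -1.86 and -3.01. T and NK cell markers differed too, 10 of 10 positive and 0 past the threshold (median 1.71, camera adjusted p = 1.5e-06, adjusted p = 0.368 with an estimated correlation). NKG7 was at 0.45 and -1.10 and perforin, PRF1, at 1.56 and -0.35. These markers lay lower in viable livers at 0 h (median -1.231, camera adjusted p = 3.91e-08, adjusted p = 0.222 with an estimated correlation). At 6 h the list did not pass (median 0.349, camera adjusted p = 0.634). Of 13 urea cycle genes 12 had a negative difference and 0 passed (median -0.76, camera adjusted p = 0.000698, adjusted p = 0.413 with an estimated correlation). CPS1 was at -1.73 ± 0.19 in viable and -0.44 ± 0.52 in nonviable livers and the histidine enzyme HAL at -1.19 and 0.18. The urea cycle list lay higher in viable livers at 0 h (median 0.384, camera adjusted p = 0.0303, adjusted p = 0.653 with an estimated correlation). At 6 h it did not pass between classes (median -0.315, camera adjusted p = 0.0922).

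Viable and nonviable livers were compared before perfusion to ask whether the classes already differed. No gene passed by edgeR (1196 at unadjusted p < 0.05), with 67 by DESeq2, 0 by limma-voom, 2 without the expression filter and up to 5 without 1 liver (viable replicate 2). Cell cycle genes lay lower in viable livers as a list (0 of 17 passed, 6 adjusted over the list alone; median -1.37, camera adjusted p = 2.08e-14, adjusted p = 0.101 with an estimated correlation). The helicase subunit MCM2 was at 2.32 ± 0.12 against 5.99 ± 0.17 CPM (-1.37 ± 0.34, adjusted p = 0.392, range 0.0188 to 0.746). Thymidylate synthase, TYMS, was at 2.69 ± 0.97 against 8.72 ± 3.00 CPM (-1.69 ± 0.42, adjusted p = 0.392, range 0.0177 to 0.739). Acute phase genes lay higher (0 of 19 passed, 0 adjusted over the list alone; median 0.75, camera adjusted p = 4.2e-08, adjusted p = 0.261 with an estimated correlation). The fibrinogen chain FGG was at 33350 against 15580 CPM (adjusted p = 0.549) and haptoglobin, HP, at 60150 against 26290 CPM (1.19 ± 0.49, adjusted p = 0.669). B and plasma cell markers lay lower (0 of 5 passed, 1 adjusted over the list alone; median -1.26, camera adjusted p = 0.000283, adjusted p = 0.05 with an estimated correlation). The plasma cell chaperone MZB1 was at 0.636 against 3.52 CPM (-2.47 ± 0.65, adjusted p = 0.446, range 0.0314 to 0.764). T and NK cell markers lay lower for 10 of 10 (1 adjusted over the list alone; median -1.23, camera adjusted p = 3.91e-08, adjusted p = 0.222 with an estimated correlation). Platelet (median -1.169, camera adjusted p = 0.00124, adjusted p = 0.222 with an estimated correlation) and macrophage markers (median -0.586, camera adjusted p = 0.0383, adjusted p = 0.75 with an estimated correlation) lay lower too, with 0 genes past the threshold in each.

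The classes were compared again at 3 h of perfusion. No gene passed by edgeR (1601 at unadjusted p < 0.05), with 80 by DESeq2, 0 by limma-voom, 2 without the expression filter and up to 6 without 1 liver (viable replicates 1 and 2). The cell cycle list again lay lower in viable livers (0 of 17 passed, 7 adjusted over the list alone; median -1.51, camera adjusted p = 2.27e-12, adjusted p = 0.286 with an estimated correlation). MCM2 was at 1.57 against 5.01 CPM (-1.67 ± 0.35, adjusted p = 0.253, range 0.00168 to 0.61) and cyclin A2, CCNA2, at -3.71 ± 0.87 (adjusted p = 0.301, range 0.0019 to 0.695).

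At 6 h of perfusion 1 gene lay higher in viable livers, the kinase PRKCD at 14.5 ± 2.26 against 6.19 ± 1.18 CPM (1.23 ± 0.21, adjusted p = 0.0484, n = 3 each), and 9 lay lower. Among these was the vitamin E carrier afamin, AFM, at 90.5 ± 5.56 against 256 ± 68 CPM (-1.5 ± 0.24, adjusted p = 0.0404). The chromatin protein HMGN2 was at 24.8 against 65.1 CPM (-1.40 ± 0.22). The antigen-presenting MR1 (-1.21 ± 0.20), the mitochondrial protease OMA1 (-1.20 ± 0.20) and the ubiquitin ligase DZIP3 (-1.70 ± 0.26) lay lower too. For each of these the classes did not overlap, which chance gives for 10% of genes at 3 against 3. Cell cycle genes again lay lower as a list (0 of 17 passed, 10 adjusted over the list alone; median -1.85, camera adjusted p = 1.2e-05, adjusted p = 0.568 with an estimated correlation; MCM2, -1.85 ± 0.35, adjusted p = 0.0564). Neutrophil markers lay higher (0 of 10 passed, 5 adjusted over the list alone; median 1.33, camera adjusted p = 0.00126, adjusted p = 0.568 with an estimated correlation), with the formyl peptide receptor FPR1 at 2.11 ± 0.41 (adjusted p = 0.0564). Hepatocyte markers lay lower (0 of 10 passed, 5 adjusted over the list alone; median -0.76, camera adjusted p = 0.00722, adjusted p = 0.279 with an estimated correlation), with APOA1 at -0.81 ± 0.24 (adjusted p = 0.126). The 10 genes became 746 by DESeq2 and 55 without the expression filter. Without viable replicates 1, 2 and 3 the count was 4, 41 and 0, and without nonviable replicates 1, 2 and 3 it was 1233, 6 and 0. The 10 calls use a spread estimated over the libraries of all times, which treats the samples of a liver as independent. With the 6 h libraries alone 0 passed, and each of the 6 named above was then at adjusted p = 0.704. Without viable replicate 3 these were at 0.196 to 0.204, and their lowest values were 3.1e-07 to 3.5e-05.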

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

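Of the tests in this part, those of library size, of shares of cells and of the pairing of nonviable replicate 2 were chosen after the result was seen, and the others before.

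Neutrophil markers fell over 6 h in all 6 livers (log2 changes -2.542 to -0.556). Library size does not account for it, since the 6 h library was the smaller one in 3 of 6 livers. A loss of all cells other than hepatocytes would lower endothelial and stellate markers alike, but the neutrophil change lay below theirs by a median of -1.433 (-2.336 to -0.554). A washout of all blood-derived white cells would lower T and NK cell markers too. The neutrophil change lay below those by a median of -2.17 (-2.795 to -1.046). Part of this gap is a rise of the T and NK score, by 0.49 to 1.845 in viable livers. In nonviable replicates 1, 2 and 3 it changed by 0.093, -0.825 and -0.416. A rise of these transcripts within the cells would hide a washout, so this comparison cannot exclude one. With the library total as the only scaling the neutrophil score fell in 6 of 6 livers (-2.837 to -0.35), which argues against the scaling. The fall was not particular to neutrophils, since macrophage markers fell in 5 of 6 livers (-2.911 to 0.08), in nonviable replicates 2 and 3 by more than the neutrophil markers. A loss of neutrophils from the tissue or a fall of these transcripts within them stays open, as a hypothesis that these data do not separate.

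Nonviable replicate 2 changed least at 6 h, with a slope of 0.246 on the mean change of the other 5 livers over all tested genes. Low depth is argued against, since 5 other livers had a smaller 6 h library. An exchange of its 0 h and 6 h libraries would give a negative slope, and the slope was 0.246. Its libraries belong to the same liver, as 3 of 3 pairs correlated best with their own liver (0.438 to 0.731). An exchange of its 3 h and 6 h libraries stays open, since correlation within a liver cannot show it and other values go both ways. Making that exchange raised the count for 6 h against 3 h over all livers from 220 to 296 genes. Its first principal component was -32.8 at 3 h and -39.93 at 6 h. Its macrophage score fell at each step in the labelled order, from 1.411 at 0 h to 0.736 and -1.5. A smaller move of the same genes stays open, since the slope was positive and the lowest slope among the other 5 livers was 0.645 (0.645 to 1.305), and no biological explanation was tested.

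More genes passed at 3 h in viable than in nonviable livers, 399 against 1. Library size is argued against, since with all libraries thinned to the smallest total 375 genes passed in viable and 1 in nonviable livers. Over all tested genes the median SD of the 3 h change was 0.266 in nonviable and 0.261 in viable livers. The ratio of 1.021 argues against a larger spread between nonviable livers for the typical gene. It does not cover the genes that respond, which were not tested apart. Both counts also come from 1 fit with a shared spread, so the ratio does not settle this explanation. A smaller change in nonviable livers stays open. Over genes the SD of the mean nonviable change was 0.641 times that of the mean viable change. The slope of the nonviable on the viable change was 0.5, and 0.823 when fitted the other way round. The SD ratio lay further from equal than in the 9 other ways of dividing the 6 livers (1 of 10 in all). No gene passed for the difference itself (0 by edgeR, 180 at unadjusted p < 0.05, 0 by DESeq2), so the 2 counts do not show that the classes differ.

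10 gene changes held a liver apart from the other 5, with a gap above Dixon's 95% value for 6 samples, where chance gives 10.1 in the 202 groups tested. At 3 h these were HILPDA (0.729; viable replicate 3 at 2.607, the others 1.281 to 1.64), HBEGF (0.641; viable replicate 3 at 6.248, the others 3.766 to 4.657) and THBD (0.681; nonviable replicate 2 at 0.707, the others 2.976 to 4.04). At 6 h they were CMKLR1 (0.628; viable replicate 2 at -1.065, the others -4.603 to -3.286), SOCS3 (0.762; viable replicate 2 at -1.586, the others 2.68 to 4.014), RELB (0.661; nonviable replicate 2 at 0.413, the others 2.722 to 3.906) and ABCG5 (0.638; nonviable replicate 2 at 0.209, the others -1.424 to -0.833). From 3 h to 6 h they were GPR34 (0.656; nonviable replicate 3 at -2.427, the others -1.701 to -1.321), FGD2 (0.703; nonviable replicate 3 at -2.71, the others -1.498 to -0.986) and KLF4 (0.799; viable replicate 2 at -1.947, the others -0.885 to -0.618).

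The 3 h change of 11 lists lay higher in viable than in nonviable livers by camera's test of the difference, which for the macrophage and the B and plasma cell markers need not mean a larger change. Adjusted p was 1.897e-10 for immediate early genes, 2.951e-11 for chaperones, 6.217e-11 for NF-kappaB genes and 4.825e-05 for p53 targets (each adjusted p = 0.376 with an estimated correlation). It was 0.0002005 for clotting control, 0.01515 for hypoxia, 2.158e-07 for T and NK cell markers and 0.04552 for B and plasma cell markers (each adjusted p = 0.311 with an estimated correlation), and 0.01518 for unfolded protein genes, 0.007831 for NRF2 genes and 0.0013 for macrophage markers (each adjusted p = 0.528 with an estimated correlation). No list held with an estimated correlation. The p53 and NRF2 lists lay lower in viable livers at 0 h (median -0.529 and -0.654, camera adjusted p = 0.00147 and 0.000627). With an estimated correlation these were at adjusted p = 0.594 and 0.533. At 3 h neither list passed between classes (camera adjusted p = 0.673 and 0.624). With a replicate block 16 lists passed. These 11 were joined by metallothioneins, higher in viable livers (0.2303 without the block, 0.03573 with it), and by 4 lists lower in viable livers. The 4 were bile acid (0.1167, 0.02193), urea cycle (0.1414, 0.0287) and drug metabolism genes (0.2376, 0.005116) and hepatocyte markers (0.2688, 0.0287). With the block and an estimated correlation together no list held (lowest adjusted p = 0.2105 at 3 h, 0.6618 or above for these 5).

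At 6 h the change of 18 lists differed. It was higher in viable livers for NF-kappaB (0.02517, 0.147 with a replicate block), interferon-stimulated (0.01008), NRF2 (0.002674), p53 (0.004379) and mitochondrially encoded genes (0.02056) and the markers of macrophages (1.615e-08), neutrophils (0.0006975) and T and NK cells (1.515e-06). With an estimated correlation the adjusted p of these were 0.773, 0.632, 0.468, 0.483, 0.673, 0.368, 0.422 and 0.368. It was lower in viable livers for acute phase (0.002585), hepatocyte plasma protein (3.771e-05), drug metabolism (0.01079), bile acid (0.02874), gluconeogenesis (0.004379), urea cycle (0.0006975), fatty acid oxidation (0.004379) and nuclear oxidative phosphorylation genes (0.004379) and the markers of hepatocytes (0.004603) and stellate cells (0.01364). With an estimated correlation those were at adjusted p = 0.483, 0.413, 0.49, 0.413, 0.413, 0.413, 0.368, 0.49, 0.332 and 0.468. Acute phase and gluconeogenesis genes lay higher and interferon-stimulated genes lower in viable livers at 0 h (camera adjusted p = 4.2e-08, 0.000112 and 5.82e-06). With an estimated correlation these were at 0.261, 0.222 and 0.533. At 6 h none of these lists passed between classes (camera adjusted p = 0.649, 0.995 and 0.649). With a replicate block cholesterol synthesis (lower; 0.1518, 0.02657 with the block) and B and plasma cell markers (higher; 0.06497, 0.01365 with the block) passed too, at 0.5938 and 0.3528 with the block and an estimated correlation. The mitochondrially encoded score went from 0.257 to 0.966 in viable replicate 3, but from -0.208 to -0.098 and from 0.007 to -0.252 in the other viable livers. In 3 cases the score of every viable liver moved down and that of every nonviable liver up. These were acute phase genes (difference of the medians -0.698) and gluconeogenesis (-0.48) at 6 h, with the adjusted p above, and drug metabolism at 3 h (-0.188; 0.8844 with an estimated correlation).

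The number of genes was also counted for other divisions of the libraries, in the fit without the replicate block. Divisions were not counted with that block, which called 2398 genes for 6 h against 3 h over all livers. For the changes over all livers 64 divisions were drawn, and the real one is set against the 32 that part every pair of a liver, while the other 32 put both libraries of some livers on the same side and gave at most 1 gene. For 3 h against 0 h the real division gave the most genes (1 of 32, 799 genes, highest other 0). For 6 h against 0 h it gave the most too (1 of 32, 4824 genes). The highest other there, 4249, is the exchange of the 0 h and 6 h libraries of nonviable replicate 2, the liver that moved least. A share of 1 of 32 argues against chance, but it is the smallest these divisions allow and was not adjusted over contrasts. For 6 h against 3 h chance stays open in this fit (2 of 32, 220 genes). Exchanging the 3 h and 6 h libraries of nonviable replicate 2 gave 296. Within a class 10 divisions exist, of which 4 part every pair, too few to exclude chance: 399 genes (1 of 4) at 3 h and 3700 (1 of 4) at 6 h in viable livers, and 1 (1 of 4) and 429 (1 of 4) in nonviable livers, with 0 as the highest other in each and in the 6 divisions that part fewer pairs. The 10 divisions of 6 livers are too few as well. The differences of change at 3 h and 6 h and the classes at 0 h and 3 h gave 0 genes in 10 of 10 divisions, and the classes at 6 h gave 10 genes (2 of 10) against a highest other of 621. That division exchanges viable replicate 2 with nonviable replicate 3 and points to a structure of the 6 h libraries, whose cause was not tested.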

How the results depend on the processing

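All alternatives here were set before the data were examined, and none was added. Counts are genes past the threshold, and the cause of a difference between tools was not tested.

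DESeq2 gave 1364 genes (3 h) and 1262 (6 h against 3 h) over all livers, 973 in viable livers at 3 h, 142 and 1325 in nonviable livers at 3 h and 6 h, 17 for the difference of the 6 h changes, and 67, 80 and 746 between classes at 0, 3 and 6 h. limma-voom with a correlation within livers gave 1573, 7582 and 2009 over all livers (3 h, 6 h, 6 h against 3 h), 887 and 6384 in viable and 17 and 924 in nonviable livers. No expression filter gave 243 and 2465 in viable livers at 3 h and 6 h, 4 in nonviable livers at 3 h, and 2, 2 and 55 between classes at 0, 3 and 6 h. The fit with a replicate block gave 1499, 7856 and 2398 over all livers, 969 and 6941 in viable and 39 and 1148 in nonviable livers. Nonviable livers fitted alone gave 124 at 6 h, and the 6 h libraries alone gave 0 between classes. RLE size factors moved no count of a contrast by over 1.5 times.

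Leaving out 1 liver gave 126 to 613 genes at 3 h, 2513 to 5223 at 6 h and 0 to 872 from 3 h to 6 h over all livers. Within viable livers it gave 1 to 460 and 1 to 4258 at 3 h and 6 h, and within nonviable livers 0 to 29 and 0 to 959. For the difference of the 6 h changes it gave 0 to 1, and between classes 0 to 5, 0 to 6 and 0 to 1233 at 0, 3 and 6 h.

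Lists past the threshold fell with an estimated correlation between genes from 12 to 5 (3 h), 14 to 0 (6 h) and 10 to 0 (6 h against 3 h) over all livers, from 11 to 3 and 13 to 0 in viable livers, from 16 to 5 and 12 to 0 in nonviable livers, and from 11, 18, 12, 11 and 7 to 0 for the differences of change at 3 h and 6 h and between classes at 0, 3 and 6 h. By fry they were 7 at 3 h and 0 for 6 h against 3 h over all livers, 6 at 3 h in viable and 3 at 3 h in nonviable livers, 0 and 0 for the differences of change, and 1, 0 and 1 between classes at 0, 3 and 6 h. With a replicate block they were 22 in viable livers at 6 h.

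Of all comparisons with an alternative, 66 gene counts stayed within 1.5 times and 70 did not. For single lists 99 tests kept their side of the threshold, 55 lost it and 4 gained it, and for named genes 2806 kept it, 553 lost it and 114 gained it, with no called sign reversed. Losses of named genes came mostly without viable replicate 3 (113), viable replicate 1 (112), nonviable replicate 3 (73) and nonviable replicate 1 (68).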

Other observations

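The results in this part were picked after the tables were seen, and no test was added for them. By 6 h the p53 and apoptosis list had 8 of 15 genes up over all livers (9 adjusted over the list alone; median 0.96, camera adjusted p = 0.00232, adjusted p = 0.485 with an estimated correlation). The unfolded protein and integrated stress list had 7 of 18 up (7 adjusted over the list alone, 8 up and 2 down with a replicate block; median 0.83, camera adjusted p = 0.0124, adjusted p = 0.495 with an estimated correlation). Lipogenesis genes had 2 of 11 down (1 up and 4 down adjusted over the list alone, 1 up and 6 down with a replicate block; median -0.54, camera adjusted p = 0.0547, 0.0402 with a replicate block). Hypoxia and clotting lists, both higher after perfusion, held with an estimated correlation at 3 h within viable livers (adjusted p = 0.0184 and 0.0262) and within nonviable livers (adjusted p = 0.024 and 0.021), as did chaperones (0.033) and NF-kappaB genes (0.033) in the nonviable ones. With a replicate block as well, of these only the clotting list held (adjusted p = 0.0499 within viable and 0.0337 within nonviable livers). From 3 h to 6 h no interferon-stimulated gene passed, and 5 of 16 rose with a replicate block (median 0.46, camera adjusted p = 0.152, 0.00233 with a replicate block). With the block and an estimated correlation together that list was at adjusted p = 0.643.

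Before perfusion the classes differed by list tests in more than the groups reported above, with no gene past the threshold. Interferon-stimulated genes were lower in viable livers for 16 of 16 members (median -1.33, camera adjusted p = 5.82e-06, adjusted p = 0.533 with an estimated correlation). Nonviable replicate 2 stood apart, with a list score of 1.874 against -0.603 and -0.002 in the other nonviable and -0.745 to -0.582 in the viable livers. Cholesterol synthesis genes were higher for 17 of 17 (median 0.56, camera adjusted p = 4.29e-06, adjusted p = 0.533 with an estimated correlation). In that list nonviable replicate 2 scored 0.41, within the viable range of 0.036 to 0.438, and the other nonviable livers -1.024 and -0.976. Gluconeogenesis genes were higher for 11 of 13 (3 adjusted over the list alone; median 0.75, camera adjusted p = 0.000112, adjusted p = 0.222 with an estimated correlation). At 3 h all 17 chaperones were higher in viable livers (0 past the threshold; median 1.52, camera adjusted p = 1.49e-09, adjusted p = 0.501 with an estimated correlation). At 6 h all 10 macrophage markers (median 1.35, camera adjusted p = 0.000126, adjusted p = 0.568 with an estimated correlation) and all 13 mitochondrially encoded genes (median 0.77, camera adjusted p = 0.00555, adjusted p = 0.927 with an estimated correlation) were higher. For the latter viable replicate 3 stood apart, with a score of 0.966 against -0.252 and -0.098 in the other viable and -0.829 to -0.113 in the nonviable livers. Drug metabolism genes were lower for 15 of 18 (2 adjusted over the list alone; median -1.01, camera adjusted p = 0.00126, adjusted p = 0.568 with an estimated correlation). Here nonviable replicate 3 stood apart, with a score of 1.481 (1.673 at 0 h). The other nonviable livers were at -0.681 and -0.062 and the viable ones at -1.151 to -0.683.

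In some lists the median and the mean or the test differed in sign, so that no direction is given for them. Among them were interferon-stimulated genes at 3 h over all livers (median -0.10, mean 0.02) and cholesterol synthesis (median -0.03, mean 0.17) and mitochondrially encoded genes (median 0.16, mean 0.02, test down) at 6 h.

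Viable replicate 2 stood apart from the other viable livers at 6 h, with an NF-kappaB change of 1.481 against 5.527 and 5.874. Without it the viable livers gave 149 genes at 3 h and 2519 at 6 h. The 10 most abundant genes held 30.8 ± 2.54% of counts in viable and 23.4 ± 3.39% in nonviable livers at 0 h (mean ± SD, n = 3 each).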
